A study of Homo sapiens with 17 samples.

How the data were processed

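RNA was measured by RNA-seq in bone marrow aspirates of patients with acute myeloid leukaemia (AML) and in CD34+ cells of healthy donors. Samples were grouped by the labels' cell type into 15 AML marrow libraries and 2 donor CD34+ libraries. RNA was extracted with the RNeasy micro kit and libraries were made with a TruSeq protocol, per the labels' protocols. The kit version, the strandedness and the use of poly(A) selection or rRNA depletion are not given in the sources used here. The submitters' processing notes name the aligner STAR 2.5.0c, Picard 2.6.0, edgeR 3.14.0 and the human genome build hg19, without saying what each tool was used for.

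A single table was deposited, with 60483 gene rows and a column for each of the 17 libraries. The header of the table names no unit. The values were taken as RPKM, reads scaled to gene length and to library size, as deposited by the authors, because the library sums differed (258704 to 1077078), each gene's values were whole multiples of a step, and that step differed by library and by gene. FPKM of whole fragments would have the same form. For 100% of the 36266 rows above 0 the values in all libraries came out as whole reads, within 1e-06 reads or a relative 1e-10, whichever was larger. The recovered reads summed to between 11971100 and 75534705 in the AML libraries and to 10677666 and 10751169 in the donor libraries. The step also gave the total each library had been scaled by. Relative to its recovered reads, that total differed between libraries by factors from 0.56 to 1.24, so the deposited values had been scaled by more than the sum of reads on genes. The lowest factor belonged to the library with the largest share of haemoglobin RNA. Gene length, where used below, was a relative length, the inverse of each gene's step, and not an annotated one. A gene with few reads can come out too short, since its step is known only up to a common factor.

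No column lacked a sample. The 28 rows whose symbol a spreadsheet had turned into a date were left out. XIST, TSIX and genes of the Y chromosome were left out of every step, 509 rows in all, which left 59946 rows. Some rows carry an Ensembl identifier before a repeated symbol, and some identifiers belong to a newer annotation than the hg19 build named in the processing notes. No genome coordinates are printed, since the reference at hand was of another build. Gene symbols are those of the table. Older symbols were matched to current ones through gene name tables, which found 502 of 507 list entries, and 470 were tested. Gene classes such as protein-coding were taken from RefSeq by symbol, and 314 of the called genes had no match there.

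The test had been planned for read counts, with a limma fallback for normalised units written beside it. That plan, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Since the values were RPKM, the fallback was used. Values were transformed to log2(RPKM + 1), so fold changes are on the log2(value + pseudocount) scale with a pseudocount of 1, which understates the change of low genes. Genes with an RPKM of at least 1 in at least 2 libraries were kept, and 16397 genes were tested with limma 3.58.1 in R 4.3.3 (empirical Bayes moderation with a mean trend) and a Benjamini-Hochberg adjusted p threshold of 0.05. No covariate was used, and the labels give none. Tested on simulated data with the real genes and library numbers, the limma step called 1.5% of 200 genes changed by a log2 fold of 1, 58.5% of those changed by 2 and 83.5% of those changed by 3, with 0 calls when no gene was changed. Fold changes of about 1 were therefore mostly not detectable with 2 donor libraries. At simulated log2 folds of 1, 2 and 3, 1, 6 and 11 unchanged genes were also called. Each gene was simulated independently, with its spread among AML libraries in both groups, and only genes with a mean log2 value above 2 were changed. Real genes vary together, so the 0 calls say little about false calls in the real data.

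The 29 gene lists, covering marrow cell types, AML genes and cell functions, were tested as groups. Each list was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, all in limma. Per library, the mean log2(RPKM + 1) over the tested members of a list was compared between groups by a two-sided exact permutation test over all 136 splits into 15 and 2 libraries, whose smallest p is 0.00735. The 8 relations among the AML libraries were tested with Pearson's r and Spearman's rho and permutation p-values from 100000 resamples. Each r was computed again without the 2 libraries farthest from the median of x. All adjusted values use the Benjamini-Hochberg method over the family named. The spread among AML libraries is given as the SD of log2(RPKM + 1) for genes with a mean of at least 10 RPKM, without a test. Permutation steps and figures used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

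The genes named in the text were chosen by a rule fixed in advance. It takes CD34, as the marker named in the labels. It takes the 12 genes with the largest positive and the 12 with the largest negative fold change that passed the test, reached a mean of 10 RPKM in the higher group, had a named symbol outside immunoglobulin, T cell receptor, HLA, sex-linked, antisense and pseudogene classes, and had every AML library on the same side of both donor libraries. It takes up to 4 members per list that passed or, where none passed, the 2 with the highest mean. It takes the BCL2 family, the genes of the 8 relations and the 15 genes with the largest SD among AML libraries, leaving out genes that can mark a person, such as HLA genes and genes with common germline deletions. Of the genes this rule takes, 1 is not reported here. Any other gene named was chosen after its values were seen.

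The alternatives tried were pseudocounts of 0.1 and 0.5, no filter, an RPKM of at least 1 in 15 libraries, an absolute log2 fold of at least 1, median-of-ratios and upper-quartile scaling, haemoglobin genes removed before rescaling to equal sums, limma-voom on the recovered reads, each library left out in turn, and a replicate block in the 4 libraries whose replicate number both groups share. Alternatives chosen after seeing the data were the deep or the shallow AML libraries alone, depth class as a covariate, reads thinned to the shallowest library, at least 10 recovered reads in 2 libraries, protein-coding genes only, the AML libraries with over 5% haemoglobin left out, the removal of haemoglobin genes at the deposited scaling, the rescaling to equal sums with those genes kept, and a lowess trend on gene length removed from each library.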

Results

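Bone marrow RNA-seq libraries of patients with acute myeloid leukaemia (AML), a cancer of immature myeloid blood cells, were compared with libraries of CD34+ cells from healthy donors. CD34 is a surface protein of blood stem and progenitor cells that is used to sort them. There were 15 AML libraries, made from whole marrow aspirates, and 2 donor libraries, made from CD34+ cells. Disease and cell sorting therefore differed together, and every difference between the groups given here covers both. Nothing in the labels states that each library came from a different person, so p-values measure only the spread between these libraries. The AML libraries held 11971100 to 75534705 recovered reads (median 59661469) and the donor libraries 10677666 and 10751169. By depth the AML libraries fell into 9 deep libraries of at least 41589442 reads and 6 shallow libraries of at most 21341602, and both donor libraries were shallow. The deep ones were AML replicates 1 to 9 and the shallow ones replicates 11 to 16. Depth class therefore cannot be told apart from anything else that followed the numbering, such as a batch. Haemoglobin genes took 0.03% to 37.75% of the summed RPKM in AML libraries (median 0.12%) and 0.1% in each donor library. Mitochondrial genes took 31.54% to 56.14% in AML libraries and 43.05% and 35.62% in the donor libraries. Across the 16397 tested genes, which are not independent replicates, the donor libraries correlated with each other at r = 0.94. Pairs of AML libraries had a median r of 0.86 (0.69 to 0.95), and pairs of an AML and a donor library a median of 0.80. No pair of libraries held identical values. The labels list the 2 donor libraries as separate samples, and the values cannot show whether they came from separate donors.

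The CD34 transcript was abundant in both donor libraries, at 38.4 and 20.4 RPKM. In AML libraries it ranged from 0.083 to 112 RPKM (37.3 ± 42.5, SD, n = 15), above both donor libraries in 5 of 15. The log2 difference of AML from donor libraries was -0.75 ± 1.39 (SE, limma adjusted p = 0.742), so CD34 itself did not separate the groups.

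The comparison of AML marrow with donor CD34+ cells asked which transcripts differed between leukaemic marrow and normal progenitors. Among the named genes that passed, AHNAK, FCGR3A, ITGAM, FGR and PRF1 had the largest positive differences and VPREB3, CLC, VPREB1 and ELANE the largest negative ones. AHNAK, a large scaffold protein, reached 83.5 ± 42.7 RPKM (SD, n = 15) in AML against 9.33 and 3.68 in the donor libraries, a log2 difference of 3.42 ± 0.56 (SE, limma adjusted p = 0.00152). ITGAM and ITGAX, integrin subunits of monocytes, macrophages and neutrophils, were higher by 3.39 and 3.12 on the log2 scale, and FCGR3A, an IgG Fc receptor of natural killer cells and some monocytes, by 3.39. FCGR3A shares most of its sequence with FCGR3B, so reads of the pair can be split between them. FGR, a kinase of myeloid cells, was higher by 3.27, and PRF1, the pore-forming protein of cytotoxic lymphocytes, by 3.24. The receptor genes EMR1 and STAB1 were higher by 3.24 and 3.07, the signalling gene RASGRP4 by 3.003, the complement receptor C3AR1 by 2.96, the chemokine receptor CX3CR1 by 2.93 and C10orf54, which encodes the immune checkpoint protein VISTA, by 2.84. Adjusted p-values of these 12 genes lay between 0.00152 and 0.0468. Each was above both donor libraries in 15 of 15 AML libraries, which the rule for naming them required.

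VPREB3 and VPREB1, genes of early B cells that encode surrogate light chain components or their partners, were lower in AML. VPREB3 measured 249 and 106 RPKM in the donor libraries and 6.14 ± 9.87 (SD, n = 15) in AML, a log2 difference of -5.39 ± 0.99 (SE, limma adjusted p = 0.00427). VPREB1 differed by -5.05 and EBF1, a transcription factor of B cell commitment, by -4.32. CLC, a protein of eosinophils and basophils, differed by -5.25, and ELANE, the neutrophil elastase of primary granules, by -4.91. The other members of this group were CMTM8 (-4.38), HMHB1 (-3.97), the apolipoprotein gene APOC1 (-3.43), the mitotic ubiquitin-conjugating enzyme UBE2C (-3.41), the histone gene HIST1H4C (-3.32), the microRNA gene MIR106B (-3.23) and the globin family gene CYGB (-3.19). Histone genes have near-identical copies, and MIR106B lies within another gene, so the reads assigned to these 2 are uncertain. Adjusted p-values of the 12 genes lay between 5.14e-05 and 0.0488, and 15 of 15 AML libraries were below both donor libraries, again by the naming rule.

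**Figure D1:**
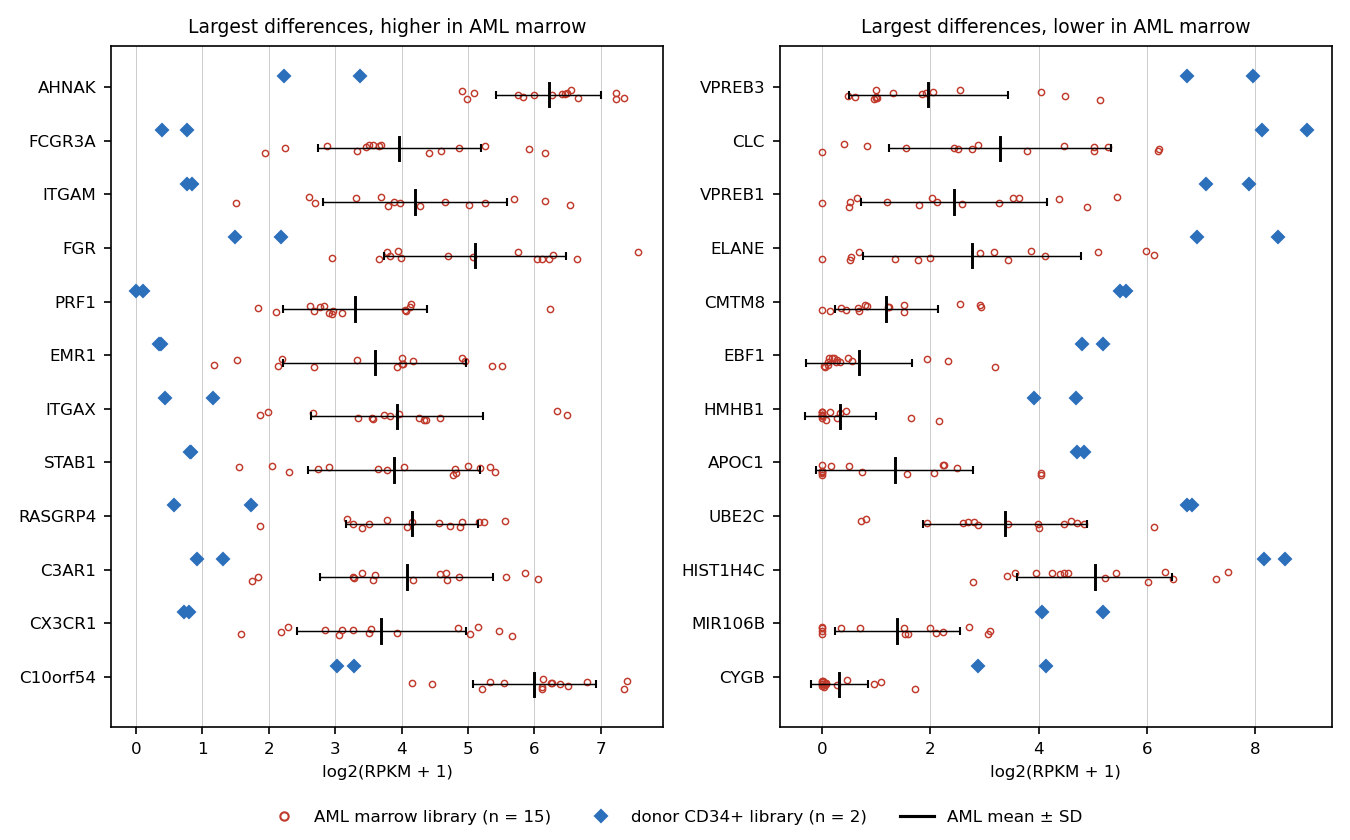
Each row is a gene and the horizontal axis is log2(RPKM + 1); open circles are the 15 AML marrow libraries, diamonds the 2 donor CD34+ libraries, and black marks the AML mean ± SD. The left panel shows the 12 largest positive differences (AHNAK 3.42 to C10orf54 2.84) and the right panel the 12 largest negative ones (VPREB3 -5.39 to CYGB -3.19). No gene shown overlaps between the groups, which the rule for naming genes required.

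Across all genes, limma called 1096 of 16397 at an adjusted p under 0.05, 265 higher and 831 lower in AML, and 4345 had an unadjusted p under 0.05. Of the called genes, 224 were higher and 642 lower with every AML library on the same side of both donor libraries. Among all tested genes, 745 had every AML library above both donor libraries and 976 had every one below, where chance gives 0.735% of genes on each side. Of the called genes that RefSeq lists as protein-coding, 230 were higher and 437 lower. The count and its split between directions depended strongly on the method, with 220 genes called by limma-voom on recovered reads (20 higher, 200 lower) and 711 with a pseudocount of 0.1 (346 higher, 365 lower). They also depended on the donor libraries, since 293 genes passed without donor replicate 1 (37 higher, 256 lower) and 122 without donor replicate 2 (2 higher, 120 lower). Of the 42 genes named by the fixed rule that passed the test, 8 passed without donor replicate 1 (AHNAK, AVP, CMTM8, CYGB, EBF1, HMHB1, RAG1 and TCF4) and 9 without donor replicate 2 (the same list without AHNAK, with CLEC4C and CXCL12). By limma-voom 14 passed, and all 42 kept their direction in each of these settings. For genes with every AML library on the same side of both donor libraries, leaving out a library cannot change the direction. Most of the 42 were such genes, so their kept direction adds little.

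**Figure D2:**
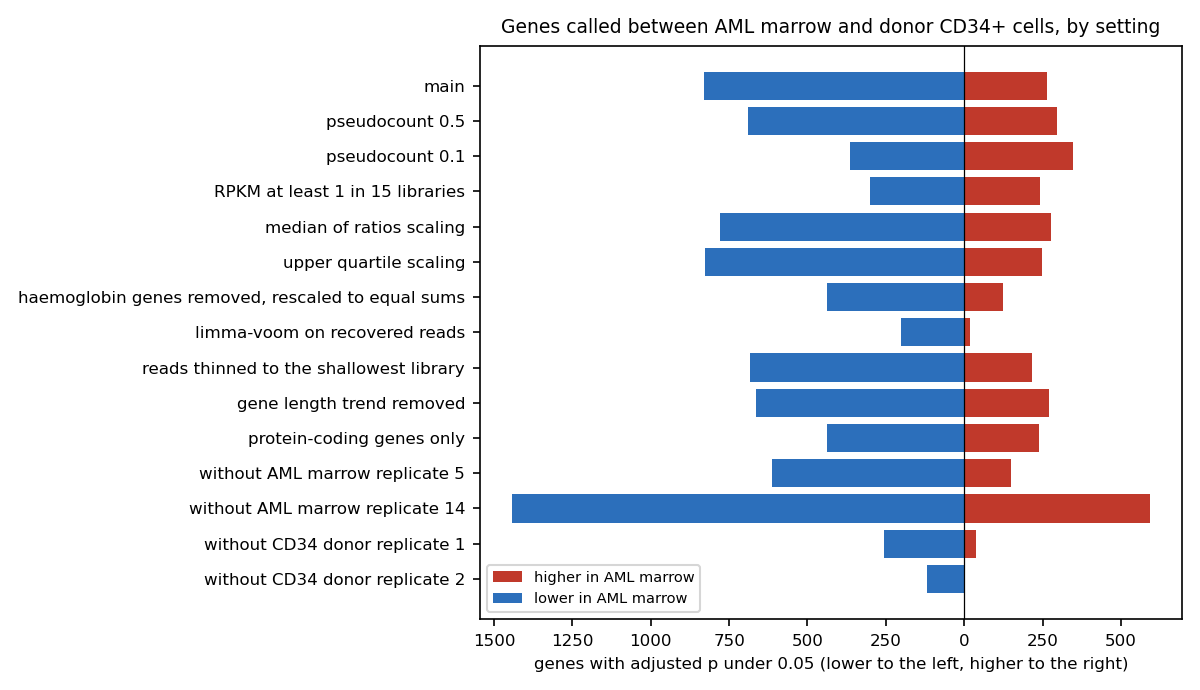
Bars give the number of genes with an adjusted p under 0.05, lower in AML marrow to the left and higher to the right, for the reported test (top, 831 lower and 265 higher) and for other settings, including the AML libraries whose absence gave the fewest (763) and the most (2037) calls. Without donor replicate 2, 120 genes were lower and 2 higher.

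Of the 16 tested members of the B cell and B progenitor list 6 were lower, 0 were higher and 10 did not pass, and 7 were lower adjusted over the list alone. EBF1, VPREB1, PAX5 (-2.91 ± 0.79, SE, limma adjusted p = 0.0354) and RAG1 (-2.74 ± 0.30, limma adjusted p = 2.79e-05), which cuts DNA in antigen receptor recombination, were among them. The camera adjusted p was 1.29e-05, with adjusted p = 0.514 with an estimated correlation, and the fry adjusted p was 0.0195. The list mean was 1.94 ± 0.67 (SD, n = 15) in AML libraries and 4.54 and 3.65 in the donor libraries, lower than both in 15 of 15 (two-sided exact permutation p = 0.00735, the smallest possible, adjusted p = 0.0711 over 29 lists). DNTT, the terminal transferase of early lymphocytes, had the widest range of these genes among AML libraries, from 0 to 406 RPKM, against 308 and 192 in the donor libraries (log2 difference -5.04 ± 1.84, limma adjusted p = 0.0968). For plasma cells 0 of 9 tested members passed (camera adjusted p = 0.858). IGJ, the joining chain of secreted antibodies, measured 95.4 ± 164 RPKM (SD, n = 15) in AML and 32.7 and 34.4 in the donor libraries, and XBP1, a transcription factor of secretory cells, 113 ± 46.6 against 122 and 119.

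In the T and NK cell list 20 of 20 members had positive differences, and PRF1 was the 1 member that passed over all genes tested, 0 were lower and 19 did not pass, and 4 were higher adjusted over the list alone. For the list as a whole camera gave adjusted p = 1.29e-05, and adjusted p = 0.624 with an estimated correlation, and the fry adjusted p was 0.220. List means were 2.51 ± 1.23 (SD, n = 15) in AML libraries and 0.79 and 0.65 in the donor libraries, above both in 15 of 15 (exact permutation p = 0.103, adjusted p = 0.230). The AML libraries ranged from 1.37 to 6.24, and the difference of 1.78 between the groups was 1.52 without AML replicate 13 and 1.29 without the 3 AML libraries over 5% haemoglobin.

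Genes of monocytes and macrophages had a list mean of 3.56 ± 1.47 (SD, n = 15) in AML libraries and 1.92 and 2.04 in the donor libraries, above both in 12 of 15 (exact permutation p = 0.162). ITGAM was higher, and 16 of 17 members did not pass. By camera the adjusted p of the list was 0.00587, and adjusted p = 0.634 with an estimated correlation. Of the mature neutrophil list 0 of 16 members passed (camera adjusted p = 0.0355, and adjusted p = 0.634 with an estimated correlation), and its mean difference fell from 1.02 to 0.54 in the shallow AML libraries, where it did not pass (camera adjusted p = 0.174). S100A9 and S100A8, calcium-binding proteins of neutrophils and monocytes, ranged in AML libraries from 4.15 to 7442 and from 1.25 to 2933 RPKM, against 44.8 and 34.2 and against 23.2 and 21.6 in the donor libraries. Of the primary granule list ELANE was lower and 11 of 12 members did not pass, while 1 was higher and 2 were lower adjusted over the list alone (camera adjusted p = 0.0352, adjusted p = 0.634 with an estimated correlation and 0.0527 with the gene length trend removed). The mean difference of this list was -1.94, and -1.66 with that trend removed. Without the AML libraries over 5% haemoglobin it was -1.76 (camera adjusted p = 0.0909). Among dendritic cell genes 2 of 8 were lower and 6 did not pass, and 3 were lower adjusted over the list alone (camera adjusted p = 0.0266, and adjusted p = 0.624 with an estimated correlation). TCF4, a transcription factor of plasmacytoid dendritic cells that progenitors also express, differed by -2.57 ± 0.36 (SE, limma adjusted p = 0.000395), and CLEC4C, a surface lectin of those cells, by -1.70 ± 0.38 (limma adjusted p = 0.0137).

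**Figure D3:**
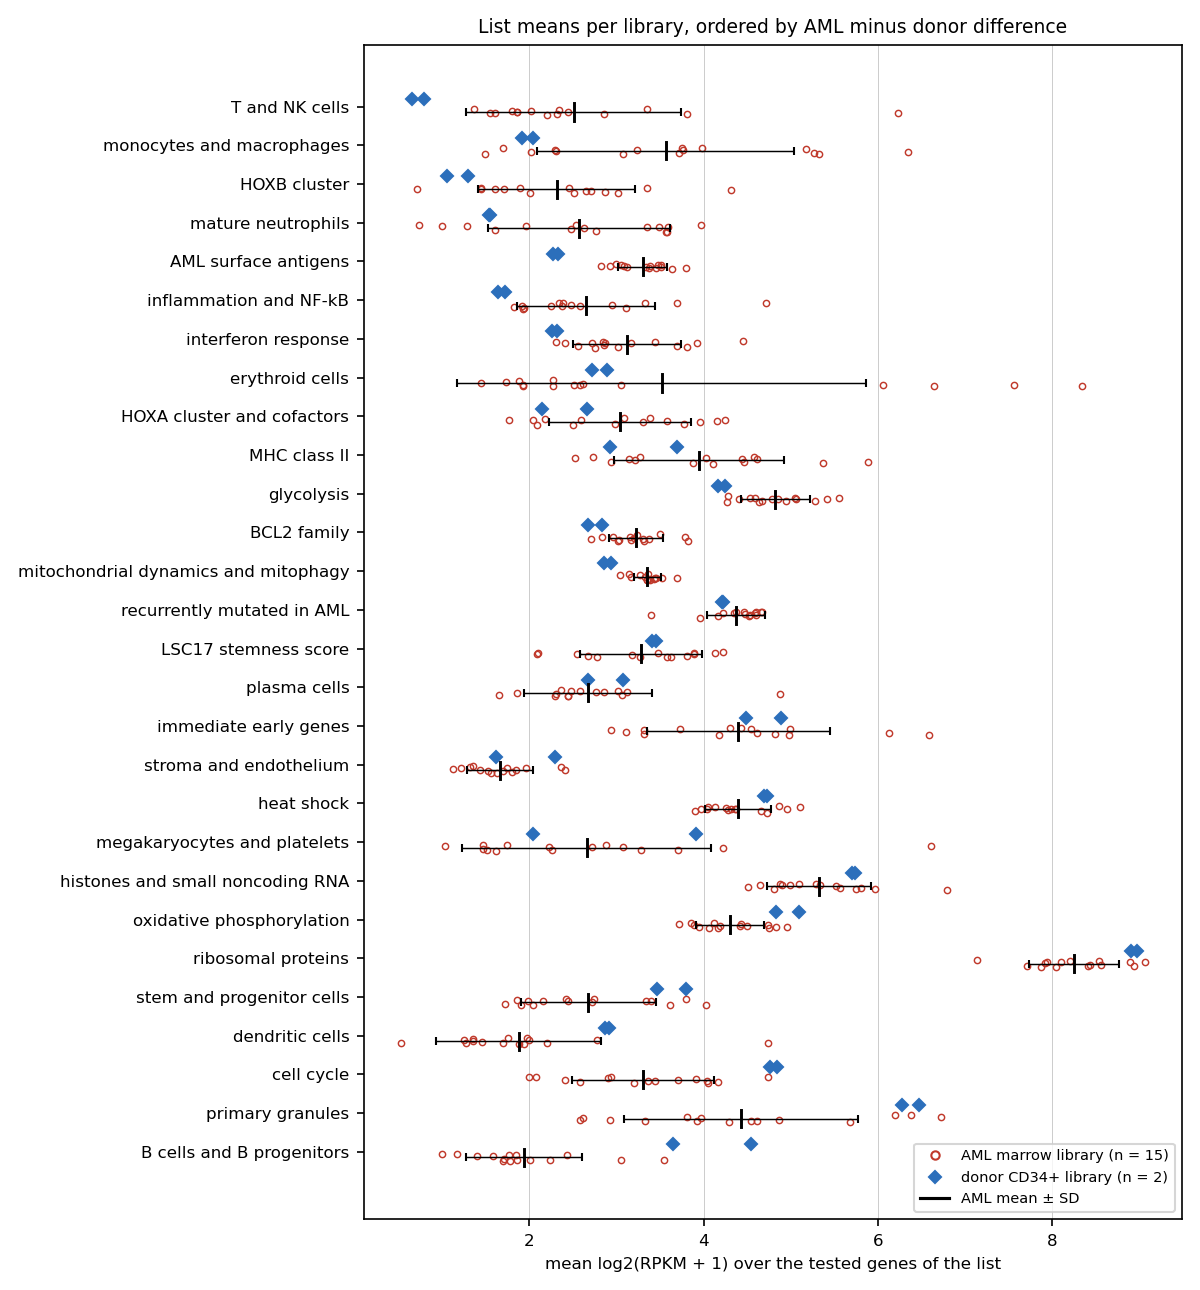
Each row is a gene list and the horizontal axis is the mean log2(RPKM + 1) over its tested genes in each library; open circles are the 15 AML marrow libraries, diamonds the 2 donor CD34+ libraries, and black marks the AML mean ± SD. Rows run from the T and NK cell list, higher in AML by 1.78, to the B cell list, lower with a difference of -2.16; the mitochondrial genome list, which lies far to the right, is not drawn.

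Of the stem and progenitor list 2 of 17 members were lower, 0 were higher and 15 did not pass. AVP and HLF, genes of the most immature stem cells, differed by -2.38 ± 0.23 (SE, limma adjusted p = 1.74e-05) and -1.21 ± 0.29 (limma adjusted p = 0.0217). Both were low, AVP at 4.30 and 5.36 RPKM and HLF at 1.79 and 2.24 in the donor libraries. The camera adjusted p of the list was 0.0260, and adjusted p = 0.624 with an estimated correlation. Its mean difference was -0.95, with -1.44 in the shallow AML libraries and -0.62 in the deep ones, where it did not pass (camera adjusted p = 0.160). With an RPKM of at least 1 in 15 libraries it was -0.45 and did not pass (camera adjusted p = 0.567; fewer genes were tested). In the 4 libraries sharing a replicate number it was -0.36 and did not pass (camera adjusted p = 0.468 with the replicate block). The LSC17 stemness score genes, a published set whose expression scores leukaemia stem cell content, had 0 of 17 members passing (camera adjusted p = 0.957). Its most abundant members, SMIM24 and CDK6, differed by -1.47 ± 0.74 (SE, limma adjusted p = 0.209) and -1.01 ± 0.58 (limma adjusted p = 0.269). Camera took the members as a plain set and the score itself was not computed, so these values do not show whether the score differed. Among the homeobox genes, 0 of 11 members of the HOXA list passed (camera adjusted p = 0.0711; 0.00162 in the shallow and 0.219 in the deep AML libraries, with mean differences of 1.09 and 0.34), with HOXA9 at 24.7 ± 17.3 RPKM (SD, n = 15) in AML and 6.87 and 12.9 in the donor libraries, HOXA5 at 39.1 ± 37.1 against 7.52 and 14.9, and HOXA10 at 28.0 ± 26.4 against 26.3 and 39.4. MEIS1, a HOX cofactor, was at 7.17 ± 4.02 RPKM against 2.06 and 1.78. Of the HOXB list 0 of 8 passed although all 8 differences were positive (camera adjusted p = 0.0355, and adjusted p = 0.624 with an estimated correlation). HOXB2 and HOXB3 differed by 1.02 ± 0.61 (SE, limma adjusted p = 0.287) and 1.61 ± 0.88 (limma adjusted p = 0.248).

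The AML surface antigens, proteins used to mark or target leukaemic cells, had a list mean of 3.2997 ± 0.28 (SD, n = 15) in AML libraries and 2.33 and 2.27 in the donor libraries, above both in 15 of 15 (exact permutation p = 0.00735, adjusted p = 0.0711). IL1RAP, the interleukin-1 receptor accessory protein, was higher by 2.24 ± 0.66 (SE, limma adjusted p = 0.0491), 0 members were lower and 15 of 16 did not pass, while 2 were higher adjusted over the list alone. The camera adjusted p was 0.00826, and adjusted p = 0.137 with an estimated correlation, and the fry adjusted p was 0.00562. IL3RA, also on the dendritic cell list, and CD99 did not reach the filter and were not tested. Both stand in rows with an Ensembl identifier before a repeated symbol, so this does not show that they were not expressed. Among the genes recurrently mutated in AML, EZH2, a histone methyltransferase, was lower by a log2 difference of -1.19 ± 0.33 (SE, limma adjusted p = 0.0391), and 24 of 25 did not pass (camera adjusted p = 0.628).

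In the BCL2 family, which controls cell death at the mitochondrion, 2 of 15 tested members were higher, 1 was lower and 12 did not pass, while 2 were lower adjusted over the list alone (camera adjusted p = 0.193). The pore-forming effectors BAX and BAK1 were higher by 1.35 ± 0.38 (SE, limma adjusted p = 0.0411) and 1.65 ± 0.43 (limma adjusted p = 0.0306), with BAX at 17.01 ± 6.75 RPKM (SD, n = 15) against 7.78 and 4.01 and BAK1 at 9.12 ± 5.14 against 2.68 and 1.36. HRK, a BH3-only activator of cell death, was lower with a difference of -0.99 ± 0.20 (SE, limma adjusted p = 0.00797) at 1.31 and 1.04 RPKM in the donor libraries. The survival gene BCL2 differed by -0.17 ± 0.44 (SE, limma adjusted p = 0.816; 0.15 with haemoglobin genes removed and libraries rescaled to equal sums, 0.087 with the rescaling alone), MCL1 by 0.53 ± 0.53 (limma adjusted p = 0.533), BCL2A1 by 1.60 ± 0.89 (limma adjusted p = 0.253), BCL2L1 by 0.82 ± 0.88 (limma adjusted p = 0.563) and BCL2L2 by 0.55 ± 0.31 (limma adjusted p = 0.254). The other members had log2 differences of 1.68 for BMF, 0.84 for BBC3, 0.72 for BCL2L11, 0.35 for BID, 0.16 for BIK, -0.90 for BAD and -1.19 for PMAIP1, with adjusted p-values from 0.0950 to 0.917.

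Genes of mitochondrial dynamics and mitophagy had a list mean of 3.35 ± 0.16 (SD, n = 15) in AML libraries and 2.94 and 2.85 in the donor libraries, above both in 15 of 15 (exact permutation p = 0.00735, adjusted p = 0.0711). CALCOCO2 and GABARAPL1, adaptor and membrane proteins of autophagy, were higher by 1.51 ± 0.42 (SE, limma adjusted p = 0.0402) and 1.80 ± 0.52 (limma adjusted p = 0.0434), 0 members were lower and 21 of 23 did not pass. The camera adjusted p was 0.0144, and adjusted p = 0.329 with an estimated correlation, and the fry adjusted p was 0.0195. Nuclear genes of oxidative phosphorylation had 0 of 28 members passing (camera adjusted p = 0.0132, direction lower, and adjusted p = 0.634 with an estimated correlation), with COX7C at 92.0 ± 80.2 RPKM (SD, n = 15) against 187 and 240 and ATP5B at 167 ± 49.3 against 140 and 108. Glycolysis genes had 0 of 20 passing (camera adjusted p = 0.0260, direction higher, and adjusted p = 0.624 with an estimated correlation). GAPDH measured 707 ± 202 RPKM (SD, n = 15) against 777 and 674, and ENO1 359 ± 160 against 228 and 258. The mitochondrial genome list had 0 of 15 passing (camera adjusted p = 0.678), and its ribosomal RNA genes MT-RNR1 and MT-RNR2 differed by 0.39 ± 0.72 (SE, limma adjusted p = 0.739) and -0.13 ± 0.85 (limma adjusted p = 0.935).

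In the cell cycle list 3 of 22 members passed, all of them lower, and 22 of 22 differences were negative. UBE2C, AURKB (-2.42 ± 0.71, SE, limma adjusted p = 0.0491), a kinase of chromosome segregation, and E2F1 (-1.70 ± 0.45, limma adjusted p = 0.0319), a transcription factor of S phase entry, were those 3, 19 did not pass, and 10 were lower adjusted over the list alone. The camera adjusted p was 1.29e-05, and adjusted p = 0.624 with an estimated correlation, and the fry adjusted p was 0.140. List means were 3.3017 ± 0.82 (SD, n = 15) in AML libraries and 4.84 and 4.77 in the donor libraries, below both in 15 of 15 (exact permutation p = 0.0147, adjusted p = 0.107). Ribosomal protein genes had 0 of 36 passing (camera adjusted p = 0.00278, direction lower, and adjusted p = 0.665 with an estimated correlation), with RPS6 at 1123 ± 349 RPKM (SD, n = 15) against 1540 and 1745. Many pseudogenes copy ribosomal protein genes, so their reads can be split. Of the histone and small noncoding RNA list HIST1H4C was lower and 12 of 13 did not pass, while 1 member was higher and 1 lower adjusted over the list alone (camera adjusted p = 0.954).

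Of the interferon response list 2 of 20 members were higher, 0 were lower and 18 did not pass (camera adjusted p = 0.00317, adjusted p = 0.624 with an estimated correlation and 0.0969 in the shallow AML libraries). These were the antiviral genes MX2, by 1.71 ± 0.46 (SE, limma adjusted p = 0.0340), and OAS1, by 1.70 ± 0.50 (limma adjusted p = 0.0477), both above the donor libraries in 15 of 15. The inflammation and NF-kB list had 0 of 17 passing (camera adjusted p = 0.0132, direction higher, and adjusted p = 0.624 with an estimated correlation), with NFKBIA at 194 ± 348 RPKM (SD, n = 15) against 70.0 and 94.3 and IL1B at 45.1 ± 41.5 against 21.2 and 29.5. Immediate early genes had 0 of 17 passing (camera adjusted p = 0.775), with ZFP36 at 366 ± 701 RPKM (SD, n = 15) against 126 and 64.6 and JUND at 152 ± 111 against 265 and 218. Heat shock genes had 0 of 9 passing, with 1 lower adjusted over the list alone (camera adjusted p = 0.789). HSP90AA1 was at 279 ± 121 RPKM (SD, n = 15) against 480 and 507 and HSPA8 at 188 ± 74.5 against 111 and 75.8. MHC class II genes had 0 of 10 passing (camera adjusted p = 0.427), with CD74 at 1072 ± 881 RPKM (SD, n = 15) against 1252 and 912 and HLA-DRA at 147 ± 205 against 73.7 and 21.3.

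Among markers of other marrow cells, 0 of 18 erythroid genes passed (camera adjusted p = 0.449). HBB and HBA2 had median values of 388 and 62.4 RPKM in AML libraries and reached 306241 and 86126.8, against 432 and 418 and against 15.7 and 16.1 in the donor libraries; HBA2 and HBA1 are near-identical copies. Megakaryocyte and platelet genes had 0 of 11 passing (camera adjusted p = 0.858), and the donor libraries differed from each other in PF4, at 236 and 29.98 RPKM, and in PPBP, at 123 and 14.6. Of the stroma and endothelium list 4 members were tested. CXCL12, a chemokine of stromal cells, was lower by a log2 difference of -1.99 ± 0.42 (SE, limma adjusted p = 0.0105), and 3 did not pass (camera adjusted p = 0.858, with a median of 0.17 and a mean of -0.29). In the donor libraries CXCL12 measured 6.77 and 2.17 RPKM. Of the 16 list calls made by camera, 10 held without donor replicate 1 (not HOXB, primary granules, mature neutrophils, dendritic cells, glycolysis or inflammation), 15 held without donor replicate 2 (not oxidative phosphorylation), 7 held among genes with an RPKM of at least 1 in 15 libraries, and 0 held with an estimated correlation. The filter on 15 libraries ended the calls of the B cell (camera adjusted p = 0.0900), AML surface antigen (0.0823) and mitophagy lists (0.0510). It also ended those of the stem and progenitor, HOXB, primary granule, mature neutrophil, glycolysis and inflammation lists. The B cell mean difference was -1.68 there, and fewer genes were tested. No list mean passed the exact permutation test after adjustment over 29 lists, where the smallest adjusted p was 0.0711.

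Relations among the 15 AML libraries were tested for 8 pairs of measures, 2 of which passed. MCL1, a survival gene of myeloid cells, followed the mean of the monocyte and macrophage list with r = 0.77 (permutation p = 0.00095, adjusted p = 0.0076) and rho = 0.76 (permutation p = 0.00169, adjusted p = 0.0135). BCL2A1, another survival gene, followed it with r = 0.68 (permutation p = 0.00485, adjusted p = 0.0194) and rho = 0.71 (permutation p = 0.0042, adjusted p = 0.0168). For BCL2 r was -0.49 (permutation p = 0.0655, adjusted p = 0.175) and rho -0.38 (permutation p = 0.169). Without the 2 libraries farthest from the median of the monocyte list mean, r was 0.61 for MCL1 (adjusted p = 0.251), 0.41 for BCL2A1 (adjusted p = 0.444) and -0.29 for BCL2 (adjusted p = 0.664), with unadjusted permutation p-values of 0.0314, 0.167 and 0.332. Neither call was kept after adjustment. Within the 9 deep libraries r was 0.78 for MCL1, 0.75 for BCL2A1 and -0.55 for BCL2, and within the 6 shallow libraries 0.91, 0.81 and -0.39. Leaving out AML replicate 4 ended both calls (r = 0.68, adjusted p = 0.08 for MCL1; r = 0.54, adjusted p = 0.173 for BCL2A1), leaving out AML replicate 7 ended that of BCL2A1 (r = 0.61, adjusted p = 0.0772), and without AML replicate 5 the relation with BCL2 passed (r = -0.68, adjusted p = 0.02).

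**Figure D4:**
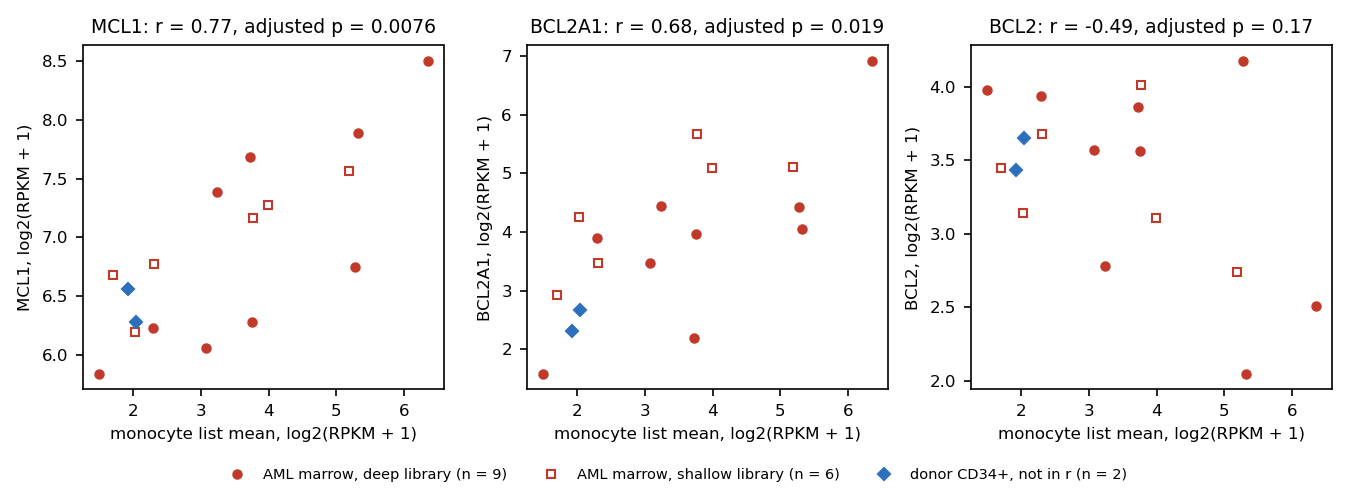
Each panel sets the monocyte and macrophage list mean (horizontal axis, log2(RPKM + 1)) against MCL1, BCL2A1 or BCL2 (vertical axis, log2(RPKM + 1)) in 9 deep (filled circles) and 6 shallow (open squares) AML marrow libraries; diamonds are the 2 donor libraries, which do not enter r. MCL1 and BCL2A1 rise with the list mean (r = 0.77 and 0.68), and BCL2 has r = -0.49.

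The other 5 relations did not pass. The monocyte list had r = -0.34 (permutation p = 0.216, adjusted p = 0.354) and rho = -0.38 (permutation p = 0.163) with the stem and progenitor list, and r = -0.17 without the 2 farthest libraries. HOXA9 had r = 0.34 (permutation p = 0.221, adjusted p = 0.354) and rho = 0.43 (permutation p = 0.114) with MEIS1, and r = 0.45 without the 2 farthest libraries. The T and NK list had r = -0.059 (permutation p = 0.844) and rho = -0.025 (permutation p = 0.933) with the cell cycle list, and r = -0.060 without the 2 farthest libraries. The erythroid list had r = 0.091 (permutation p = 0.746) and rho = 0.089 (permutation p = 0.753) with the stem and progenitor list, and r = 0.033 without the 2 farthest libraries. The mitophagy list had r = -0.19 (permutation p = 0.504) and rho = -0.10 (permutation p = 0.724) with the oxidative phosphorylation list, and r = 0.0019 without the 2 farthest libraries. Adjusted p-values of the last 3 were 0.844, 0.844 and 0.672.

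Expression differed widely among the AML libraries. Over 3942 genes with a mean of at least 10 RPKM the median SD of log2(RPKM + 1) was 0.55. The 15 genes with the largest SD were red cell, myeloid and early lymphoid genes and 3 rows named only by clone. The haemoglobin genes HBA1, HBA2, HBB, HBG2 and HBM had SDs of 4.15, 4.02, 3.64, 3.42 and 2.87, and the red cell genes AHSP, a haemoglobin chaperone, and SLC4A1, an anion exchanger, SDs of 3.32 and 2.85. The myeloid genes S100A8, S100A9, LYZ and S100A12 had SDs of 3.11, 3.07, 2.87 and 2.77, with LYZ, which encodes lysozyme, between 24.0 and 12802 RPKM against 724 and 662 in the donor libraries. DNTT had an SD of 2.79. The clone rows FP236383.10, FP671120.4 and RP5-857K21.11 had SDs of 3.35, 3.22 and 2.97. The first 2 had medians of 0.52 and 0.42 RPKM and belong to near-identical copies, so their reads are uncertain. Per list, the SD of the list mean among AML libraries was largest for the erythroid list (2.35) and was 1.47 for monocytes and macrophages, 1.43 for megakaryocytes and platelets and 0.16 for mitochondrial dynamics and mitophagy.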

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

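Tests chosen after seeing the data were those on the deep or shallow AML libraries, depth as a covariate, thinned reads, the minimum of 10 reads, protein-coding genes, the AML libraries with over 5% haemoglobin left out, the gene length trend, and the removal of haemoglobin genes and the rescaling to equal sums each alone. The 2 donor libraries limit every group comparison, and depth was lower in them (10677666 and 10751169 reads) than in any AML library. All 1096 called genes kept their direction under both other scalings, both other pseudocounts, limma-voom and each library left out in turn. For the 866 of them with every AML library on the same side of both donor libraries, leaving out a library could not change it. No values are given for the edgeR and DESeq2 alternatives, because the deposited unit is RPKM and whole reads could be recovered from it only up to a common factor for each gene, which limma-voom shares as a limit. When tried on those reads, edgeR called far fewer genes than limma did and DESeq2 called more, most of them higher in AML, so neither the number of calls nor the excess of lower ones should be taken as settled. The main test called 1096 genes (265 higher, 831 lower). With median-of-ratios and upper-quartile scaling it called 1056 and 1075, with a pseudocount of 0.5 it called 988, with thinned reads 899, and with the length trend removed 936 (271 higher, 665 lower). The count moved with a pseudocount of 0.1 to 711 (346 higher, 365 lower), with no filter to 1819 (1569 lower), with an RPKM of at least 1 in 15 libraries to 541 (241 higher, 300 lower; fewer genes were tested), with haemoglobin genes removed and libraries rescaled to equal sums to 563 (125 higher, 438 lower), with that rescaling alone to 537 (69 higher, 468 lower) and with limma-voom on recovered reads to 220 (20 higher, 200 lower). Removing haemoglobin genes at the deposited scaling gave 1105 calls, so the change came with the rescaling, which replaces the scaling of the submitters. The median log2 fold of all genes was 0.0084, 0.24 with both steps, 0.20 with the rescaling alone, 0.0078 with the removal alone and -0.11 with limma-voom. The count moved with depth as a covariate to 715 (152 higher), in the shallow AML libraries to 367 (52 higher, 315 lower), in the deep ones to 1571 (398 higher), among protein-coding genes to 676 (437 lower; fewer genes were tested), and without the 3 AML libraries over 5% haemoglobin to 2171 (610 higher, 1561 lower). Apart from fewer genes or libraries and the rescaling, the cause of these changes was not tested.

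Leaving out 1 library gave 122 to 2037 calls (2 to 593 higher, 120 to 1444 lower): 293 without donor replicate 1, 122 without donor replicate 2, 1854 without AML replicate 13, 2037 without AML replicate 14, and 763 to 1398 without any other AML library. Where 1 donor library was left out, the lone one was assumed to vary like the AML libraries. Of the 42 named called genes, 26 to 42 passed without 1 AML library. In the 4 libraries with a replicate number shared by both groups, limma called 0 genes with the replicate block and 0 without it, 0 higher and 0 lower, while 2822 and 2385 had an unadjusted p under 0.05; donors and patients are different people, so a shared number does not pair them. Of 29 lists, 16 passed with camera at the preset correlation, 0 with an estimated correlation, 3 by fry, 7 with an RPKM of at least 1 in 15 libraries, and 10 to 17 with 1 library left out (10 without donor replicate 1). Under alternatives chosen after seeing the data, calls of these 16 lists ended as follows, with camera adjusted p. In the shallow AML libraries these were the mature neutrophil (0.174) and interferon lists (0.0969), and with depth as a covariate the same lists (0.309 and 0.105) and glycolysis (0.0840), while the HOXA list passed in both (0.00162 and 0.00582). Both donor libraries were shallow, so with the covariate the estimated differences were those of the shallow libraries (1.09 for HOXA in both). The 2 settings differ in the variance and are not separate support. Calls that ended in the deep AML libraries were the stem and progenitor (0.160), HOXB (0.174) and dendritic cell lists (0.0945), among protein-coding genes HOXB (0.0761), mature neutrophils (0.0912) and glycolysis (0.0710), and with the length trend removed primary granules (0.0527) and glycolysis (0.0704). Without the AML libraries over 5% haemoglobin these were HOXB (0.0855), primary granules (0.0909), mature neutrophils (0.114) and dendritic cells (0.0579). Among protein-coding genes the mean differences of HOXB, mature neutrophils and glycolysis were those of the main test (1.14, 1.02 and 0.62). With the length trend removed they were -1.66 for primary granules and 0.57 for glycolysis, against -1.94 and 0.62 in the main test. The list means gave 0 passing lists with the mean, the median or z scores over members and with median-of-ratios scaling; with 1 donor library left out the splits are too few for any list to pass, so no test was made. Of the 8 relations 2 passed, 2 with median-of-ratios scaling, 0 without the 2 farthest libraries, and 0 to 3 with 1 AML library left out (0 without AML replicate 4, 1 without AML replicate 7, 3 without AML replicate 5). Of the 15 genes with the largest SD, 6 were among the 15 with the largest median absolute deviation, and 15 remained with a mean of at least 1 RPKM.

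Among the values of single named genes, lists and relations under the alternatives chosen in advance, 3341 kept their direction and side of the threshold, 391 kept only their direction and no longer passed, and 13 passed that had not; under alternatives chosen after seeing the data these were 1110, 103 and 7. Genes and lists that did not pass the test changed sign as follows, and none that passed did; the cause was tested only for the haemoglobin genes. In the 4 libraries with or without the replicate block, log2 differences were 0.10 for AHSP, 0.21 for BCL2, -0.052 for BCL2L11, 0.45 for CD34, 3.42 for FP236383.10, -0.50 for FP671120.4, -0.085 for HLA-DRA, 0.015 for HOXA10, -0.78 for IGJ, -1.06 for LYZ, -0.17 for MCL1, -0.11 for MT-RNR1, -0.12 for NFKBIA, -0.16 for PPBP, -0.51 for ZFP36 and 0.43 for the LSC17 list. In the deep AML libraries they were -0.34 for BIK, 0.26 for CD34, 0.0064 for GAPDH, -0.25 for IGJ, -0.50 for PPBP and 0.051 for the immediate early list. In the shallow AML libraries, and likewise with depth as a covariate, they were -0.24 for FP671120.4, -0.82 for LYZ, 0.13 for MT-RNR2, -0.085 for ZFP36, 0.17 for the megakaryocyte list, 0.024 for the mitochondrial genome list and 0.11 for the plasma cell list. With the length trend removed they were 0.15 for MT-RNR2 and 0.034 for the mitochondrial genome list. With haemoglobin genes removed and libraries rescaled to equal sums they were 0.15 for BCL2, 0.25 for GAPDH, 0.21 for MT-RNR2, 0.13 for XBP1, 0.15 for the LSC17 list, 0.032 for the mitochondrial genome list and 0.016 for the plasma cell list. With the rescaling alone they were 0.087 for BCL2, 0.18 for GAPDH, 0.14 for MT-RNR2, 0.064 for XBP1 and 0.11 for the LSC17 list, and with the removal alone none changed sign. With limma-voom they were -0.35 for BIK, -0.69 for FP671120.4 and -0.082 for PPBP. Without the AML libraries over 5% haemoglobin they were 0.00073 for GAPDH, -0.32 for HBB, -0.50 for PPBP and -0.28 for the erythroid list. With 1 library left out, values ranged from -0.0020 to 0.29 for BIK, -0.68 to 1.52 for FP671120.4, -0.19 to 0.013 for GAPDH, -0.31 to 0.057 for MT-RNR2, -2.84 to 0.098 for PF4, -1.27 to 1.72 for PPBP, -1.26 to 0.61 for the megakaryocyte list, -0.40 to 0.0066 for the plasma cell list and -0.63 to 0.051 for the stroma list. The r of the T and NK list with the cell cycle list ranged from -0.24 (without AML replicate 3) to 0.27 (without AML replicate 13), that of the erythroid list with the stem and progenitor list from -0.18 to 0.33 and that of the mitophagy list with the oxidative phosphorylation list from -0.29 to 0.085, and the last was 0.0019 without the 2 farthest libraries.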

Other observations

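Genes outside the fixed rule, named after their values were seen, showed 2 more differences. B2M, the light chain shared by all MHC class I proteins, measured 203 RPKM on average in AML libraries and 24.6 and 26.7 in the donor libraries (log2 difference 2.79 ± 0.50, SE, limma adjusted p = 0.00333), and was above both in 15 of 15. Some other genes of the MHC class I pathway, taken from no fixed list, did not pass: TAP1 differed by 1.47 ± 0.44 (limma adjusted p = 0.0519), PSMB8 by 1.27 ± 0.46, NLRC5 by 1.04 ± 0.37 and PSMB9 by -0.27 ± 0.38. MS4A2, a chain of the IgE receptor of mast cells and basophils, differed by -1.85 ± 0.34 (limma adjusted p = 0.00460), like CLC a gene of granulocyte types other than neutrophils, while the mast cell genes CPA3 (0.33 ± 1.34) and TPSAB1 (0.23 ± 1.09) did not pass.

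In this part all tests except that on B2M, namely the tests on gene length, the pseudocount, the spread of AML-high genes in its final form, B cell stages, single donor libraries, the sort, PRF1 and library depth, and the splits of the libraries, were chosen after the result they bear on was seen. The 1096 calls were set against other splits of the 17 libraries into 15 and 2. Of 100 splits drawn, the real one included, 1 gave as many calls, the real one itself, and the highest of the others gave 527. The real split thus gave more calls than any other split drawn, though not every possible split was drawn. The 2 donor libraries were the only sorted ones and correlated at r = 0.94, against a median of 0.86 for AML pairs. A split that sets such a pair apart can rank first whatever made the pair alike. This ranking therefore cannot exclude chance, and it does not tell disease from cell sorting or from 2 similar libraries.

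Lower calls outnumbered higher calls 3.136 to 1. Of the called genes that RefSeq lists as protein-coding, 230 were higher and 437 lower, so part of the excess lay among other or unmatched rows. The lower calls clustered among genes inferred to be short, with 281 in the shortest of 5 length groups and 103 in the longest. Length was inferred from the step of each gene's values, so genes with few reads can come out too short. A bias with this inferred length alone is argued against, since with each library's length trend removed the ratio was 2.45. A pseudocount of 1 on low values may account for part of the excess, because the ratio was 1.05 with a pseudocount of 0.1. By contrast, limma-voom on recovered reads, which does not add that pseudocount, called 200 lower and 20 higher genes. DESeq2 on those reads called mostly higher genes, so the excess itself depended on the method. Whether a larger spread of AML-high genes among AML libraries added to it cannot be told: among genes with a log2 difference of at least 2 in size the median SD over AML libraries was 1.39 for the 132 positive and 1.12 for the 455 negative ones, a ratio of 1.24, yet 0.773 among the 67 and 120 of them with an AML median of at least 10 RPKM. The pseudocount narrows the SD of negative ones, which lie nearer 0, while a floor on the median favours negative ones with a wide spread.

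The mean of the B cell and B progenitor list, of which 6 of 16 genes passed, was lower in every AML library than in both donor libraries, although with an estimated correlation camera did not call the list (adjusted p = 0.514). Fewer B lineage cells of every stage cannot be told apart from a change in early stages alone. MS4A1, BANK1, BLK, FCRLA and CD22, taken here as mature B cell genes, differed by a mean of -0.50 (exact permutation p = 0.324). Their mean was below both donor libraries in 10 of 15 AML libraries. These genes were not shown to be confined to mature cells, and the called genes, picked for being lower, are no yardstick for them. A single donor library as the source is argued against by the mean over the whole list, which differed from donor replicate 2 alone by -1.71, with 15 of 15 AML libraries below it. The first measure chosen, called genes above every AML library in the weaker donor library, gave only 3 of 6 and would have counted for that source; it was replaced after that was seen, so the measures disagree and this argument is weak. Cell sorting of the donor libraries and the disease cannot be told apart, since the series as analysed here holds 0 libraries of sorted AML cells or of unsorted healthy marrow, and the difference of patients from healthy donors stays open, untested.

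T and NK cell genes were higher in every AML library by list mean, by less (1.29 in place of 1.78) without the 3 libraries over 5% haemoglobin; whether admixed blood contributed was not tested. The deep libraries as the only source are argued against, because the mean log2 difference of the list was 2.01 in the 6 shallow AML libraries alone, all of them above both donor libraries. Those 6 include AML replicate 13, with 37.75% haemoglobin, without which the difference over all AML libraries was smaller. Even the shallowest AML library, with 11971100 reads, was deeper than both donor libraries, so depth was not matched. Whether T and NK cells present in the unsorted marrow, which a CD34 sort would remove, were the source cannot be told: PRF1 followed the mean of the other 19 list genes over the 15 AML libraries with r = 0.90 (permutation p = 7e-05), but the list genes vary together (estimated correlation 0.853), and any source of these transcripts would give that. The list's most abundant gene NKG7 measured 64.9 RPKM on average in AML and 21.6 and 20.4 in the donor libraries, and expression of the list by leukaemic cells was not tested.

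A hypothesis that B2M is higher with the interferon response was tested on the AML libraries, with the test chosen before its result was seen. B2M had r = 0.27 (permutation p = 0.327) and rho = 0.16 (permutation p = 0.572) with the mean of the interferon list over 15 libraries, r = -0.078 without the 2 farthest libraries, 0.28 in the deep and 0.22 in the shallow libraries. The test found no relation, which with 15 libraries does not show that there is none. An interferon effect shared by all AML libraries would leave no such relation, so the source of the B2M difference stays open.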
